A study of Mus musculus with 6 samples.

How the data were processed

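Gene expression was measured by RNA sequencing in 6 libraries of LKPR EPCAM+ cells, a line derived from a mouse skin squamous cell carcinoma with loss of Trp53 and a YFP lineage reporter. Per the labels, the cells had been transduced with a lentiviral vector that was empty or that knocked down Unc5b or Ntn1, and there were 2 libraries in each of the 3 groups. Cells had been cultured for 6 days and living YFP and EPCAM positive cells were sorted before RNA was extracted with a column kit and turned into libraries with the Ovation Solo system. Nothing in the sources used here says that the 2 libraries of a group came from separate cultures or transductions.

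The deposited values were treated as a score, because the authors' table holds whole numbers that sum to about 20 M in every library and so are scaled and rounded values, not raw read counts. The submitters' processing notes name STAR, Picard and HTSeq, with no versions, and the GRCm38 (mm10) build. The annotation, the counting settings, the strand setting, the handling of duplicate reads and the scaling step are not given in the sources used here. The table lists 49671 genes by Ensembl identifier and symbol, and 49326 of the identifiers were found in the GENCODE M21 annotation of GRCm38, from which gene positions were taken. Because the strand setting is not given, reads of a gene and of a gene whose exons overlap it on the other strand cannot be told apart. Overlaps of exons were found without regard to strand, so they also include genes on the same strand.

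The depth was estimated from the spacing of low values. In each library the values up to 150 were whole multiples of a fixed step within a rounding tolerance of 0.5, and the step gives what 1 read is worth. The step was 1.97 and 2.29 in the empty vector libraries, 2.38 and 3.06 in the Ntn1 knock-down and 2.14 and 2.32 in the Unc5b knock-down. A step close to 2 leaves a large share of whole numbers within the tolerance by chance, so the multiples alone do not prove the step. Dividing the totals by the steps gives 10.2 and 8.75 M reads for the empty vector, 8.41 and 6.54 M for the Ntn1 knock-down and 9.36 and 8.64 M for the Unc5b knock-down. A floor of 3 reads corresponds to 5.90 to 9.17 in the scaled unit, and this floor covers counting error only. The step was estimated and is not known exactly, for example 2.2847 to 2.2868 in empty vector library 2. Whole reads at higher values are therefore uncertain, and no count model was fitted.

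Values were analysed as deposited on the scale log2(value + 5), over the 15330 genes with a mean of at least 20 across the 6 libraries. A log2 fold change on this scale understates the change of genes at low values. Fold values given for single genes are instead ratios of group means as deposited, without the 5 added. They can differ from the log2 fold changes where a gene is low or the libraries of a group are far apart. Counts of called genes that differed at least 2-fold used the log2 fold change. A linear model with 3 groups was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3, with a trend of the variance on mean expression, 3 residual degrees of freedom and 5.33 prior degrees of freedom. The tests were 2-sided and the p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called changed at an adjusted p under 0.05. The comparisons were Ntn1 knock-down against empty vector, Unc5b knock-down against empty vector, Ntn1 against Unc5b knock-down, and the overlap of the comparisons with the empty vector. The design had been written for counts or for scaled values before the data were examined, and the branch for scaled values was used.

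The overlap was set against the number that independent lists would share and against 100 simulated draws of unchanged groups that share the same control libraries. Almost no gene is called in such draws, so they are no null for the number shared. They hold only the spread within groups, so they show the correlation and covariance that this spread alone gives. With 2 control libraries the controls could not be split. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so none was used for single genes.

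Gene lists were fixed before the data were examined, 22 in all. They included netrin ligands and receptors, epithelial markers, mesenchymal and extracellular matrix markers, EMT transcription factors, keratinocyte differentiation, cell cycle, apoptosis regulators, TGF-beta response, YAP and TAZ targets, inflammatory cytokines and NF-kB targets, interferon response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, unfolded protein and integrated stress response, heat shock and immediate early genes, p53 targets, Wnt pathway targets, and markers of fibroblasts, immune cells, endothelial cells, and melanocytes and nerve. Some genes stand in more than 1 list, such as Ntn1 in the netrin and the YAP and TAZ lists. The netrin list also holds genes that encode neither a netrin nor a netrin receptor, such as Dapk1, Flrt2 and Rgma. The 21 lists with at least 5 members among the genes tested were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation and with fry. Counts of list members are given over all genes tested and adjusted over the list alone.

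Genes are named by a rule fixed before the data were examined. It takes Ntn1, Unc5b and the markers Epcam, Cdh1, Krt14, Trp63, Vim, Zeb1, Zeb2, Prrx1 and Snai2 whatever their values. For each comparison with the empty vector it takes the 10 highest and the 10 lowest fold changes among called genes with a mean of at least 100 over the 4 libraries compared and no overlap between the groups. It takes 5 and 5 for the comparison of the knock-downs and for the genes called in both. For each list it takes up to 4 members, the 2 highest and the 2 lowest among those called, or the 2 with the smallest p where none was called. Gene models without a usual symbol were skipped. Results on some genes and on 1 list were left out of the text because the items are withheld for evaluation. Other genes that the text names were chosen after their values were seen, and this is said where they appear.

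The model was tested on simulated reads with the means and depths of the real libraries. Every gene and group had the same assumed spread, and genes were drawn independently. The results therefore do not cover unequal spread or lists with correlated members. In the simulated Ntn1 comparison, over 15311 genes, 4 of 67 genes changed 1.5-fold were called, 27 of 67 genes changed 2-fold (40.3%) and 60 of 66 genes changed 4-fold (90.9%), and 2 of 15087 unchanged genes were called. A simulated list of 30 genes shifted 1.5-fold had an adjusted p of 7.85e-18 there, and 0 of the other 21 lists were called.

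The alternatives tried were TMM and median-of-ratios scaling, no filter and a minimum mean of 100, pseudocounts of 1 and 20, limma without the trend, the replicate number as a block, a fit of the 4 libraries compared, a 2-fold threshold with and without the test, and leaving out each library in turn. Alternatives added after the data were seen were a rescaling without rRNA-annotated and mitochondrial genes, the Malat1 level as a covariate, voom weights on estimated reads, and lists without Ntn1 and Unc5b. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. Reads were not analysed here.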

Results

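RNA was sequenced from LKPR EPCAM+ cells, an epithelial cell line from a mouse skin squamous cell carcinoma. The cells carried an empty lentiviral vector, a knock-down of Ntn1, which encodes the secreted ligand netrin-1, or a knock-down of Unc5b, which encodes a netrin receptor. Each of the 3 groups had 2 libraries, made after 6 days of culture from sorted living cells positive for YFP and EPCAM. The series title concerns the targeting of netrin-1 and the epithelial-to-mesenchymal transition, so the comparisons ask what lowering the ligand or a receptor did to epithelial, mesenchymal and other gene groups. All values are scaled to 20 M reads per library as deposited, and levels are given in that unit as mean ± SD over n = 2 libraries. Estimated depth was 10.2 and 8.75 M reads in the empty vector libraries 1 and 2, 8.41 and 6.54 M in the Ntn1 knock-down and 9.36 and 8.64 M in the Unc5b knock-down, and 22639 to 23183 genes per library were above 0. Libraries of a group correlated at r = 0.980 for the empty vector, 0.990 for the Ntn1 and 0.986 for the Unc5b knock-down across genes, against 0.936 to 0.967 between groups. The libraries of a group are not stated to come from separate cultures, so the p-values measure only the spread between these libraries, which may be technical, and an exact permutation test of 2 against 2 libraries could not go below 0.333.

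The targeted genes were lower in the libraries labelled with their knock-down. Ntn1 (ENSMUSG00000020902, chromosome 11, 68209364 to 68400823 on the minus strand of GRCm38) was at 1566 and 2588 in the empty vector libraries, 359 and 431 in the Ntn1 knock-down and 1319 and 771 in the Unc5b knock-down. It was 5.26-fold lower in the Ntn1 knock-down (log2 fold change -2.34 ± 0.29 SE, limma adjusted p = 0.00162). In the Unc5b knock-down it did not pass (-0.99 ± 0.29, adjusted p = 0.0638), although it did with TMM scaling (adjusted p = 0.0413) and median-of-ratios scaling (0.0477), without empty vector library 1 (0.0142) and without Unc5b knock-down library 1 (0.0413). Unc5b (ENSMUSG00000020099, chromosome 10, 60762593 to 60831581 on the minus strand) was at 1527 and 1573 in the empty vector libraries, 419 and 352 in the Unc5b knock-down and 2311 and 2382 in the Ntn1 knock-down. It was 4.02-fold lower in the Unc5b knock-down (-2.0 ± 0.13, adjusted p = 0.000252) and 1.51-fold higher in the Ntn1 knock-down (0.60 ± 0.13, adjusted p = 0.0193). The rise of Unc5b in the Ntn1 knock-down lost its call without Ntn1 knock-down library 1 (adjusted p = 0.15) or 2 (0.177), with no filter (0.0516) and without the variance trend (0.0636).

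**Figure D1:**
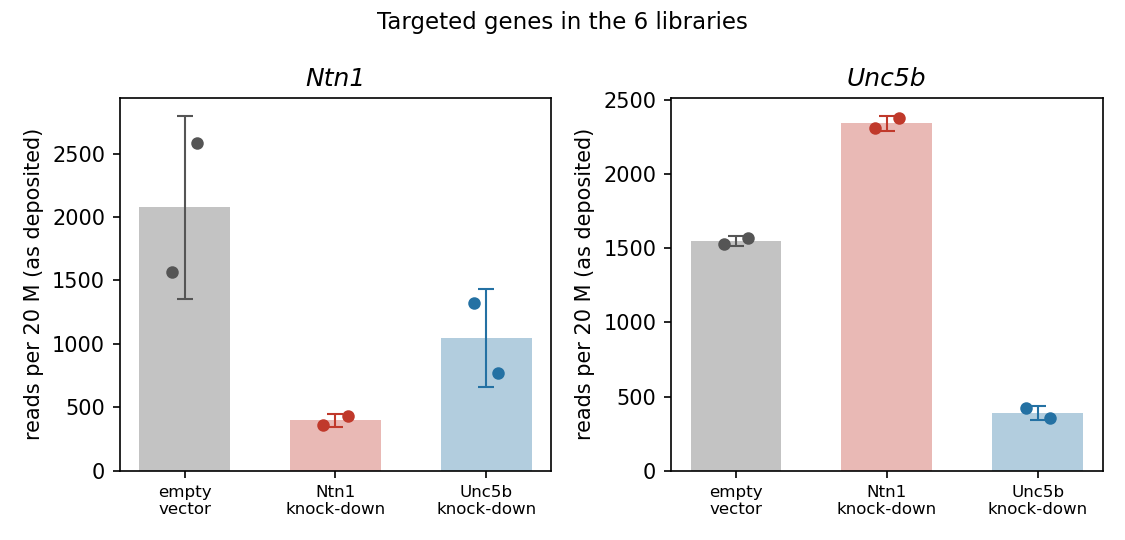
Ntn1 and Unc5b in each of the 6 libraries, in reads per 20 M as deposited. Points are libraries and bars are group means ± SD (n = 2). Ntn1 lay at 359 and 431 in the Ntn1 knock-down against 1566 and 2588 in the empty vector, and Unc5b at 419 and 352 in the Unc5b knock-down against 1527 and 1573.

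The comparison of the Ntn1 knock-down with the empty vector asks what lowering the ligand changed. Krt6a, a keratin of wounded epidermis (chromosome 15, 101689910 to 101694307), rose from 10.5 ± 4.9 to 760 ± 41 (log2 fold change 5.66 ± 0.45, adjusted p = 0.000276), and Stfa3, a cysteine protease inhibitor, was listed at 0 in both empty vector libraries and at 223 ± 22.6 in the knock-down. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), rose 32-fold to 1729 ± 297, and Serpinb2, a plasminogen activator inhibitor, rose 27.4-fold to 2956 ± 582. Krt6a, Serpinb2 and Fras1 overlap exons of other annotated genes, on a strand that was not checked. Their values are uncertain, because neither the counting settings for overlaps nor the strand setting is given. Among the genes that fell most were Apob, which encodes apolipoprotein B (45-fold lower, from 1124 ± 253), Fras1, a basement membrane protein (from 595.5 ± 389.6 to 9.5 ± 0.7), and Scnn1a, a subunit of the epithelial sodium channel (14.8-fold lower, from 941 ± 755.2).

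Among genes that met the naming rule, the remaining large rises in the Ntn1 knock-down included Cyfip2, a component of the WAVE actin regulatory complex, at 332.5 ± 70. Auts2 was at 311 ± 7.1, the mannose receptor gene Mrc1 at 306.5 ± 61.5 and Disp2 at 244 ± 22.6. In the empty vector these 4 genes lay at or below 3 ± 1.4. Slco4a1, an organic anion transporter listed at 0 in the empty vector, was at 221.5 ± 54.4, and Adamts14, a procollagen peptidase, rose from 28 ± 28.3 to 863.5 ± 94. Ppp2r2c, a phosphatase regulatory subunit, was 51.5-fold lower than its empty vector level of 1446 ± 15.6, the water channel gene Aqp5 was 11.3-fold lower and Psapl1 13.5-fold lower. Plekhg1 (21.6-fold), Ndnf (16.6-fold) and Nrp1, a co-receptor for semaphorins and vascular growth factors (12.7-fold), were also lower. The empty vector libraries 1 and 2 were far apart for Nrp1, at 1439 and 4898, for Ndnf, at 141 and 606, and for Plekhg1, at 281 and 606. The limit of overlapping exons also holds for Nrp1, Zeb1, Zeb2, Tmem47, Pcdh19, Rspo3, Trps1, Map2, Hhip, Foxf2, Tgm1, Fbn1, Twist2, Nusap1, Bmp4, Il1a, Psmb8, Scd2, Pdia6, Jun and Cdkn1a. It holds as well for Axin2, Rgma, Unc5c, Gas1, Sox4, Fst, Thbs1, Elovl6, Wnt7b, Egfl7, Ncam1, Dsg2, Lox, Spp1, Pfkp, Bhlhe40, Tigar and Lef1.

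Epithelial and mesenchymal genes moved in both directions in the Ntn1 knock-down. Over all genes tested, 2314 of 15330 were called in this comparison, a share against which the counts of list members are to be read. All libraries were made from cells sorted as EPCAM positive, so cells that had lost EPCAM were not measured in any group. The level of Epcam and of these lists describes the sorted cells only. Epcam (8684 ± 922.1 and 9931.5 ± 276.5), the E-cadherin gene Cdh1 (7939.5 ± 678.1 and 9073.5 ± 433.5) and Krt14 (2804.5 ± 1573.3 and 5014 ± 309.7) did not pass, and neither did Vim, which encodes vimentin (842 ± 367.7 and 1055 ± 65.1, adjusted p = 0.442). Of 57 epithelial markers measured, 13 rose and 9 fell (14 and 12 adjusted over the list alone), with Krt17 rising 30.6-fold and the transcription factor gene Ehf 20-fold, and Krt19 2.82-fold and Trp63 2.97-fold lower. Of 43 mesenchymal and extracellular matrix markers, 11 rose and 10 fell (17 and 11 adjusted over the list alone). The collagenase and stromelysin genes Mmp13 (14.8-fold) and Mmp3 (17.1-fold) rose, and Fbn1, which encodes fibrillin (7.25-fold), and Col12a1 (6.99-fold) were lower. Of 23 EMT transcription factors, 4 rose and 6 fell (6 and 6 adjusted over the list alone). Zeb2 rose 2.25-fold (adjusted p = 0.00501) and Prrx1 2.08-fold (adjusted p = 0.000879), whereas Twist2 was 3.76-fold and Foxc1 3-fold lower. Zeb1 (32.5 ± 9.2 and 37 ± 25.5) did not pass, and Snai2 was below the filter at 10 and 27 in the empty vector and 40 and 28 in the knock-down. None of these 3 lists passed with camera, at adjusted p = 0.172 for the epithelial, 0.174 for the mesenchymal and 0.995 for the transcription factor list, and the last had a median log2 fold change of 0.04, a mean of -0.12, camera direction up and fry direction down. The mesenchymal list passed, upward, without empty vector library 2 (adjusted p = 0.00784). Trp63 lost its call without either Ntn1 knock-down library (adjusted p = 0.105 and 0.122) and with no filter (0.0702), Zeb2 lost its call without library 2 (0.0789), and Krt14 passed without empty vector library 1 (0.0172).

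**Figure D2:**
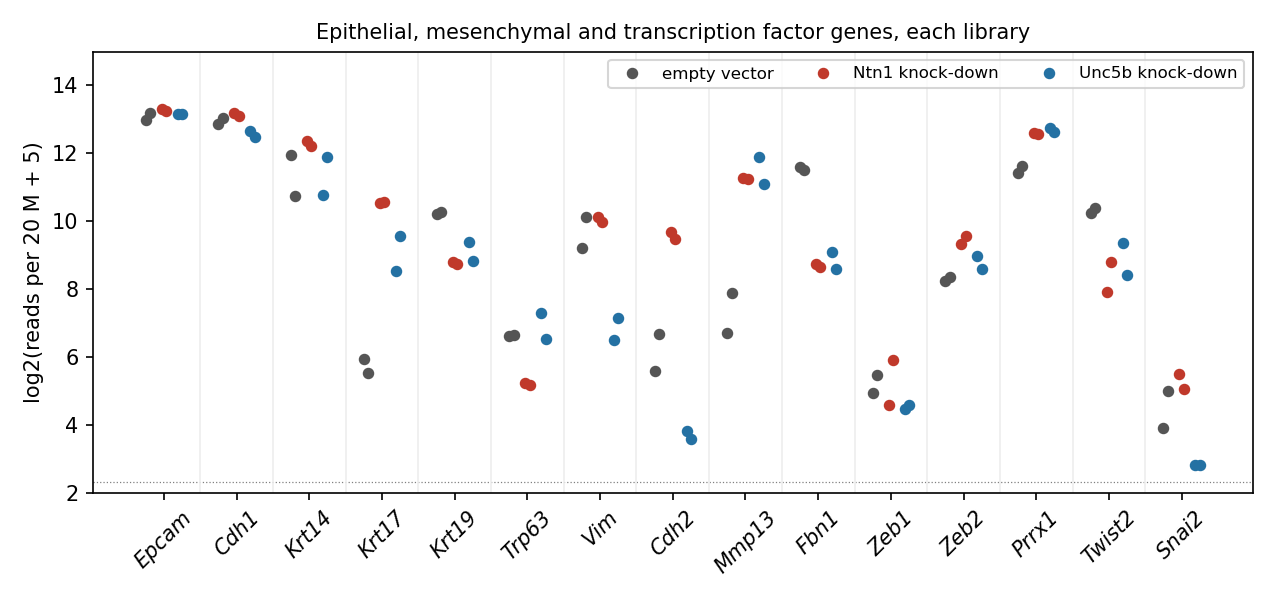
Epithelial, mesenchymal and transcription factor genes in each library, as log2 of the value per 20 M plus 5. Points are libraries, coloured by group, and the dotted line marks a value of 0. Cdh1 is lowest in the Unc5b knock-down libraries, as are Vim and Cdh2, and Krt17 is higher in both knock-downs than in the empty vector.

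Of 29 inflammatory cytokines and NF-kB targets, 16 rose and 3 fell in the Ntn1 knock-down (18 and 4 adjusted over the list alone), among them Il1a, which encodes interleukin-1 alpha and rose 9.79-fold to 10516 ± 31.1. Ccl7 was listed at 0 in the empty vector and at 74.5 ± 37.5 in the knock-down, while the chemokine genes Cxcl12 (15.8-fold) and Cxcl3 (2.53-fold) were lower. The list passed with camera (adjusted p = 3.68e-07) but not with an estimated correlation (adjusted p = 0.354), with a range of 2.46e-08 to 0.354 over the alternatives. With fry the inflammatory list passed (adjusted p = 0.0148). Of 25 keratinocyte differentiation genes, 12 rose and 3 fell (15 and 5 adjusted over the list alone), with Krt6a and Stfa3 highest and the cornified envelope enzyme gene Tgm1 (10.4-fold) and Ly6d (88.5 ± 81.3 to 5.5 ± 0.7) lowest. Its adjusted p was 0.00112, and adjusted p = 0.354 with an estimated correlation, with a range of 8.03e-05 to 0.354. With fry the keratinocyte list passed (adjusted p = 0.0184). Among markers of other cell types, 3 of 28 immune cell markers reached the filter, too few for a list test. These 3 genes were chosen after their values were seen. Csf1r fell by 1.77 on the log2 scale (adjusted p = 0.00193), while Cd14 (adjusted p = 0.126) and Cd68 (0.106) did not pass.

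Of 24 YAP and TAZ targets, 1 rose in the Ntn1 knock-down (Nt5e, 1.7-fold) and 9 fell (1 and 10 adjusted over the list alone), including Foxf2 (5.95-fold lower), Asap1 (1.57-fold lower) and the targeted gene Ntn1 itself. The list passed (adjusted p = 0.000806), but gave adjusted p = 0.73 with an estimated correlation and 0.122 with fry, with a range of 4.67e-06 to 0.73. Of 32 cholesterol and fatty acid synthesis genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone), among them the desaturase genes Scd2 (4-fold lower) and Scd1 (3.76-fold lower), Stard4 (1.86-fold lower) and Ebp (1.96-fold lower). Its adjusted p was 0.00529, and adjusted p = 0.746 with an estimated correlation, 0.355 with fry and 0.0988 without empty vector library 1, with a range of 0.000324 to 0.746.

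The other lists did not pass with camera in the Ntn1 knock-down, and counts adjusted over the list alone stand in brackets. Of 21 Wnt pathway targets, 4 rose and 8 fell (5 and 12), with Nkd2 4.68-fold and Tcf7 3.85-fold higher and the stem cell receptor gene Lgr5 (182.5 ± 197.3 to 7 ± 2.8) and Axin2 (11.2-fold) lower (adjusted p = 0.12). Of 32 TGF-beta response genes, 4 rose and 9 fell (6 and 12), with Inhba 2.75-fold and Pmepa1 1.9-fold higher and Bmp4 (180.5 ± 119.5 to 7 ± 2.8) and Id2 (5.99-fold) lower (adjusted p = 0.249). Of 13 members of the netrin list, 3 rose and 1 fell (4 and 6), with Dapk1, a death-associated kinase, 18.3-fold and Flrt2 9.7-fold higher beside Unc5b (adjusted p = 0.705). Dapk1 and Flrt2 encode neither a netrin nor a netrin receptor. Of 27 heat shock and immediate early genes, 3 rose and 9 fell (5 and 11), with Hspb1 7.4-fold and Jun 2.43-fold higher and Fos 2.62-fold and Klf4 2.33-fold lower (adjusted p = 0.172). Of 53 cell cycle genes, 0 rose and 2 fell (0 and 1), Bub1b (1.34-fold lower) and Nusap1 (1.77-fold lower), at adjusted p = 0.12. Of 37 apoptosis regulators, 3 rose and 3 fell (3 and 3), with Birc3 1.82-fold higher and the death receptor gene Fas 5-fold and Bcl2l1 1.57-fold lower (adjusted p = 0.705). Of 36 hypoxia and glycolysis genes, 7 rose and 3 fell (7 and 3), with Car12 5.77-fold and Egln3 3.2-fold higher and Pdk1 2.44-fold lower (adjusted p = 0.26).

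Of 38 genes of the unfolded protein and integrated stress response, 4 rose and 4 fell in the Ntn1 knock-down (7 and 4 adjusted over the list alone), with the cystine transporter gene Slc7a11 2.3-fold higher and Pdia6 2.13-fold lower (adjusted p = 0.552). Of 19 p53 targets, 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely Cdkn1a (2.5-fold), Sesn2 (1.51-fold) and Mdm2 (1.32-fold), at adjusted p = 0.128 with camera and 0.0184 with fry. The genotype of the cells includes a conditional loss of Trp53. Of 28 interferon response genes, 1 rose (Psmb8, 2.94-fold) and 3 fell (1 and 2 adjusted over the list alone), Ifit2 being lower at 8.5 ± 4.9 against 100 ± 32.5 (adjusted p = 0.239). Of 5 fibroblast markers, 0 rose and 1 fell (1 and 1 adjusted over the list alone), Twist2 (adjusted p = 0.794). Of 7 endothelial markers, 1 rose (1 and 0 adjusted over the list alone), Cdh5, listed at 0 in the empty vector and at 99.5 ± 19.1 in the knock-down (adjusted p = 0.267 with camera, 0.0414 with fry). Of 5 melanocyte and nerve markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone), Mitf (4.39-fold lower) and Mbp (1.74-fold lower), at adjusted p = 0.128 with camera and 0.0184 with fry. Without empty vector library 1 the Wnt list passed (adjusted p = 0.0356), and without library 2 the cell cycle (8.03e-05) and heat shock (0.0154) lists. The cell cycle list also passed without Ntn1 knock-down library 1 (0.0157).

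In all, limma called 2314 of 15330 genes changed in the Ntn1 knock-down against the empty vector, 1232 higher and 1082 lower, and 1099 of them differed at least 2-fold. The count was 1289 with no filter, 1462 without the variance trend, 509 without Ntn1 knock-down library 1 and 540 without library 2, where the lone library is assumed to vary like the other groups. Of 86 calls of named genes, 38 were lost without either Ntn1 knock-down library, 36 with no filter and 24 without the variance trend, and 0 changed direction. The Ntn1 knock-down libraries also had more of their total in rRNA-annotated genes (5.50% and 6.26%) than the empty vector (4.75% and 4.68%) and less in ribosomal protein genes (1.85% and 1.90% against 2.28% and 2.43%).

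The comparison of the Unc5b knock-down with the empty vector asks what lowering the receptor changed, and 2 matrix metalloproteinase genes were among those that rose most. Mmp9, a gelatinase gene (chromosome 2, 164940780 to 164955850), rose 35.2-fold to 3116 ± 77.8, and Mmp13 rose 18.1-fold to 2998 ± 1161.1. Tmem47 rose 39.6-fold to 1425 ± 79.2, and the leptin receptor gene Lepr was at 3 ± 4.2 in the empty vector and at 361.5 ± 72.8 in the knock-down. The protocadherin gene Pcdh19 (chromosome X, 133582860 to 133688987) fell from 1004 ± 190.9 to 6.5 ± 3.5 (log2 fold change -6.48 ± 0.26, adjusted p = 3.32e-05), and the Wnt agonist gene Rspo3 from 260 ± 94.8 to 1 ± 1.4. Vim fell 7.58-fold, from 842 ± 367.7 to 111 ± 36.8 (adjusted p = 0.00124).

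The other genes with the largest rises in the Unc5b knock-down were Fggy (to 201.5 ± 71.4), Zfp334 (21.5-fold), the interleukin-13 receptor gene Il13ra2 (21.7-fold), Serpinb2 (20.2-fold), Adamts14 (14.7-fold) and Emp3 (18.5-fold). Serpinb2 was at 806 and 3555 in the Unc5b knock-down libraries 1 and 2. The largest falls included the chemokine gene Cxcl12, at 4 and 0 in the knock-down. In the empty vector libraries Cxcl12 was at 126 and 777. Flt4, a receptor of lymphatic growth factors, was 33.6-fold lower, Nrp1 22.1-fold, the microtubule-associated protein gene Map2 21.8-fold, the hedgehog inhibitor gene Hhip 22.7-fold and Foxf2 22.4-fold. The transcription repressor gene Trps1 fell from 373 ± 239 to 7 ± 2.8.

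Epithelial and mesenchymal genes moved in both directions in the Unc5b knock-down, again among cells sorted as EPCAM positive only. Over all genes tested, 1835 of 15330 were called in this comparison, a share against which the counts of list members are to be read. Epcam (9153.5 ± 46), Cdh1 (6082.5 ± 514.1, adjusted p = 0.0675), Krt14 (2788 ± 1455.2) and Trp63 (120 ± 45.3) did not pass. Of 57 epithelial markers, 7 rose and 5 fell (8 and 11 adjusted over the list alone), with Krt17 11.4-fold and Ehf 8.07-fold higher and Mal2 3.61-fold and Krt19 2.16-fold lower (camera adjusted p = 0.484). The median of this list was -0.05 and its mean 0.10, with camera and fry direction down. Of 43 mesenchymal and extracellular matrix markers, 7 rose and 14 fell (10 and 18 adjusted over the list alone), with Mmp9 and Mmp13 highest and Col12a1 (12.3-fold) and Gas1 (11.9-fold) lowest (adjusted p = 0.111). The libraries of a group were far apart for Gas1, at 77 and 281 in the empty vector and 28 and 2 in the knock-down. Of 23 EMT transcription factors, 4 rose and 7 fell (4 and 8 adjusted over the list alone), with Prrx1 2.24-fold and Sox4 1.95-fold higher and Twist1 4.42-fold and Klf4 3.07-fold lower (adjusted p = 0.413). Its median was 0.01 and its mean -0.22, with camera and fry direction down. Zeb2 (438 ± 82, adjusted p = 0.135) and Zeb1 (18 ± 1.4, adjusted p = 0.41) did not pass, and Snai2 was at 2 in both libraries. Without empty vector library 1 Cdh1 passed, downward (adjusted p = 0.0368), and the mesenchymal list passed without empty vector library 1 (0.0246) and without Unc5b knock-down library 1 (0.0464).

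Of 29 inflammatory cytokines and NF-kB targets, 16 rose and 1 fell in the Unc5b knock-down (20 and 1 adjusted over the list alone), with Il1a 10.9-fold and the monocyte chemokine gene Ccl2 7.17-fold higher and Cxcl12 as the member that fell. The list had adjusted p = 1.54e-09, but adjusted p = 0.359 with an estimated correlation, with a range of 3.14e-11 to 0.359 over the alternatives. With fry the inflammatory list passed (adjusted p = 0.00958). Of 25 keratinocyte differentiation genes, 8 rose and 3 fell (11 and 3 adjusted over the list alone), with Serpinb2 and S100a8 (4.5 ± 3.5 to 77.5 ± 2.1) highest and Cdsn, which encodes corneodesmosin (5.92-fold), and Klk10 (2.12-fold) lowest. Its adjusted p was 0.0139, and adjusted p = 0.623 with an estimated correlation, with a range of 0.00124 to 0.623. With fry the keratinocyte list passed (adjusted p = 0.0413). Of the 3 immune cell markers measured, 0 passed, Csf1r being at 1569 and 1003.

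Of 24 YAP and TAZ targets, 0 rose and 6 fell in the Unc5b knock-down (2 and 11 adjusted over the list alone), including Foxf2, Dlc1 (3.86-fold), Cyr61 (1.66-fold) and Wwc1 (1.54-fold). The list had adjusted p = 0.00032, but adjusted p = 0.761 with an estimated correlation and 0.202 with fry, with a range of 2e-06 to 0.761. Of 13 members of the netrin list, 0 rose and 3 fell (1 and 6 adjusted over the list alone), namely Unc5b itself, the receptor gene Unc5c (93 ± 79.2 to 1 ± 1.4) and Rgma (3.12-fold). This list had adjusted p = 0.00786, but adjusted p = 0.761 with an estimated correlation, 0.209 with fry, 0.111 with Ntn1 and Unc5b left out and 0.176 without empty vector library 2, with a range of 0.000441 to 0.761.

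The other lists did not pass with camera in the Unc5b knock-down, and counts adjusted over the list alone stand in brackets. Of 21 Wnt pathway targets, 2 rose and 6 fell (5 and 8), with Nkd2 3.02-fold and Wnt7b 1.35-fold higher, Axin2 lower at 6.5 ± 6.4 against 212 ± 188.1, and Lgr5 at 2 in both knock-down libraries against 43 and 322 in the empty vector (adjusted p = 0.131). Of 32 TGF-beta response genes, 3 rose and 9 fell (7 and 11), with Fst 2.71-fold and Tgfbr1 1.61-fold higher and Bmp4 5.81-fold and the thrombospondin gene Thbs1 3.11-fold lower (adjusted p = 0.26). Of 27 heat shock and immediate early genes, 6 rose and 5 fell (8 and 7), with Hspb1 6.3-fold and Klf2 2.77-fold higher and Klf4 and Ier2 lowest (adjusted p = 0.896). Of 53 cell cycle genes, 0 rose and 0 fell by limma (0 and 0), and the smallest p-values were those of Nusap1 (adjusted p = 0.0601) and Mki67 (0.0651), at adjusted p = 0.26 for the list. Of 37 apoptosis regulators, 3 rose and 1 fell (3 and 1), with Casp1 2.57-fold, Pmaip1 1.79-fold and Bcl2l11 1.7-fold higher and Fas 2.11-fold lower (adjusted p = 0.409). Of 36 hypoxia and glycolysis genes, 1 rose (Hk2, 1.77-fold) and 6 fell (1 and 6), with Aldoc 6.8-fold and Egln3 3.47-fold lower (adjusted p = 0.111). Of 32 cholesterol and fatty acid synthesis genes, 0 rose and 1 fell (0 and 1), Elovl6 (1.62-fold lower), at adjusted p = 0.298.

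Of 38 genes of the unfolded protein and integrated stress response, 2 rose and 3 fell in the Unc5b knock-down (2 and 4 adjusted over the list alone), with Slc7a11 1.84-fold higher and the serine synthesis gene Phgdh 3.02-fold lower (adjusted p = 0.47). Of 19 p53 targets, 2 rose and 1 fell (2 and 1 adjusted over the list alone), Pmaip1 and Zmat3 higher and Perp lower, with a median of -0.01 and a mean of 0.04 (adjusted p = 0.959). Of 28 interferon response genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone), Ifit2 (to 7.5 ± 10.6) and Gbp3 (5.81-fold lower), at adjusted p = 0.45. Of 5 fibroblast markers, 1 rose (Lsp1, 3.55-fold) and 1 fell (1 and 1 adjusted over the list alone), Twist2, with median 0.15, camera direction down and fry direction up (adjusted p = 0.959). Of 7 endothelial markers, 0 passed (0 and 0 adjusted over the list alone), Lyve1 (adjusted p = 0.183) and Egfl7 (0.671) having the smallest p, at adjusted p = 0.83. Of 5 melanocyte and nerve markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone), Ncam1 (4.22-fold lower) and Mitf (4.69-fold lower), with a median of 0.11 and a mean of -0.64 (adjusted p = 0.175 with camera, 0.00958 with fry). Without empty vector library 1 the TGF-beta and Wnt lists passed, and without library 2 the cell cycle and hypoxia lists. Without Unc5b knock-down library 1 the cholesterol and Wnt lists passed, and without library 2 the cell cycle list. These fits left 1 library in a group and used the preset correlation of 0.01. The estimated correlation was 0.532 for the cell cycle and 0.591 for the cholesterol list.

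**Figure D3:**
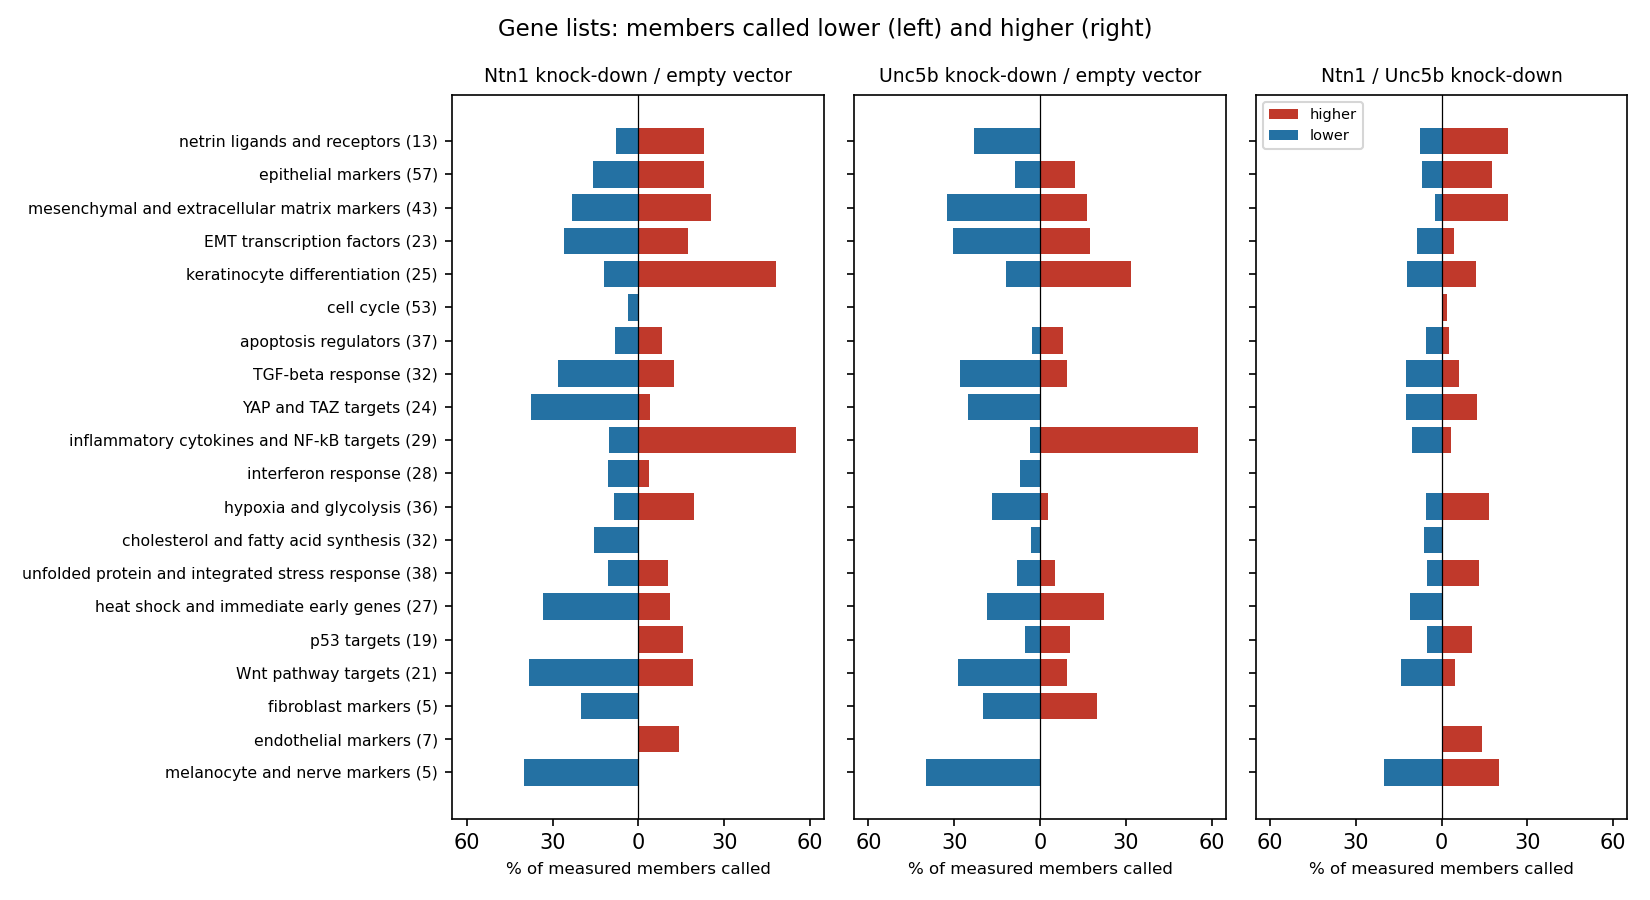
Share of the measured members of each list called higher (right) or lower (left) in each comparison, in percent, with the number of measured members in brackets. Of 29 inflammatory genes 16 were higher in each knock-down than in the empty vector, and 1 was higher in the Ntn1 than in the Unc5b knock-down.

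In all, limma called 1835 of 15330 genes changed in the Unc5b knock-down against the empty vector, 904 higher and 931 lower, and 939 of them differed at least 2-fold. The fit assumes 1 spread for all 3 groups. The median SD within a group on the log2 scale was 0.182 for the empty vector, 0.105 for the Ntn1 and 0.151 for the Unc5b knock-down. The count of 1835 therefore rests in part on the lower spread of the Ntn1 knock-down libraries, which are not compared here. The count was 791 with no filter, 1115 without the variance trend and 950 with only the 4 libraries compared. It was 992 and 669 without Unc5b knock-down library 1 and 2, and 978 and 971 without Ntn1 knock-down library 1 and 2. Of 78 calls of named genes, 20 and 34 were lost without Unc5b knock-down library 1 and 2, 37 with no filter and 24 without the variance trend, and 0 changed direction.

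The knock-downs were also compared with each other, which tests whether they differ, as the comparisons with the control do not. Stmn2, a microtubule regulator of neurons (chromosome 3, 8509360 to 8561606), was at 1185 ± 1.4 against 8 ± 8.5 in the Unc5b knock-down (log2 difference 6.69 ± 0.47, adjusted p = 0.000858). Cdh2, which encodes N-cadherin (chromosome 18, 16588877 to 16809246), was at 760 ± 72.1 against 8 ± 1.4 (5.88 ± 0.37, adjusted p = 0.000774), with 70.5 ± 38.9 in the empty vector. Vim was at 1055 ± 65.1 against 111 ± 36.8 (3.23, limma adjusted p = 0.00151). Cdh1, taken here after its value was seen, was at 9073.5 ± 433.5 against 6082.5 ± 514.1 (0.58 ± 0.12, adjusted p = 0.0228), and it lost its call without Ntn1 knock-down library 1 (0.25) or 2 (0.181), without Unc5b knock-down library 1 (0.0638) or 2 (0.138), with no filter (0.0834) and without the variance trend (0.104). Pcdh19, Trps1 (425.5 ± 47.4 against 7 ± 2.8) and Cyfip2 were the other genes with the largest differences upward among those that met the naming rule. Lower in the Ntn1 knock-down were Ppp2r2c (15.9-fold), the meiotic cohesin gene Stag3 (9.5 ± 0.7 against 192 ± 17), Klf2 (5.92-fold), Tgm1 (5.08-fold) and Scd1 (5.59-fold). The Unc5b knock-down libraries 1 and 2 were far apart for Scd1, at 925 and 292.

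Over all genes tested, 1088 of 15330 were called between the knock-downs, a share against which the counts of list members are to be read. Of 43 mesenchymal and extracellular matrix markers, 10 were higher in the Ntn1 than in the Unc5b knock-down and 1, Spp1, was lower (14 and 4 adjusted over the list alone), with Cdh2 and the collagen cross-linking enzyme gene Lox (248.5 ± 4.9 against 9 ± 5.7) highest. The list had adjusted p = 0.000129, but adjusted p = 0.567 with an estimated correlation and 0.126 with fry, with a range of 2.81e-05 to 0.567. Of 57 epithelial markers, 10 were higher and 4 lower (17 and 7 adjusted over the list alone), with the desmoglein genes Dsg3 (15.4-fold) and Dsg2 (5.8-fold) highest and Trp63 (3.75-fold) and Cldn6 (1.85-fold) lowest. That list had adjusted p = 0.00286, but adjusted p = 0.567 with an estimated correlation and 0.126 with fry, with a range of 0.000515 to 0.567. Of 13 members of the netrin list, 3 were higher and 1 lower (5 and 1 adjusted over the list alone), Flrt2 (12.3-fold), Dapk1 (7.74-fold), Unc5b (6.09-fold) and, downward, Ntn1 (2.65-fold). Its adjusted p was 0.00106, with adjusted p = 0.567 with an estimated correlation and 0.126 with fry, with a range of 0.00021 to 0.567. Of 36 hypoxia and glycolysis genes, 6 were higher and 2 lower (10 and 2 adjusted over the list alone), with Egln3, an oxygen-sensing hydroxylase gene (11.1-fold), and Pfkp (1.83-fold) highest and Pdk1 and Bhlhe40 lowest. Its adjusted p was 0.00121, with adjusted p = 0.567 with an estimated correlation and 0.105 with fry, with a range of 0.000502 to 0.567. Trp63 lost its call without Ntn1 knock-down library 1 (adjusted p = 0.143) or 2 (0.156), without Unc5b knock-down library 1 (0.111) and with no filter (0.0779).

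The other lists did not pass in the comparison of the knock-downs, and counts adjusted over the list alone stand in brackets. Of 32 cholesterol and fatty acid synthesis genes, 0 were higher and 2 lower in the Ntn1 knock-down (0 and 2), Scd1 and Ebp (adjusted p = 0.0573). Of 27 heat shock and immediate early genes, 0 were higher and 3 lower (0 and 4), Klf2, Fosb and Fos (0.0948). Of 37 apoptosis regulators, 1 was higher and 2 lower (1 and 3), Dapk1 against Fas and Pmaip1 (0.107), and of 38 unfolded protein and stress response genes 5 were higher and 2 lower (7 and 2), with Phgdh 2.41-fold higher and Pdia6 2.27-fold lower (0.108). Of 19 p53 targets, 2 were higher and 1 lower (3 and 1), Tigar and Perp against Pmaip1 (0.159). Of 25 keratinocyte differentiation genes, 3 were higher and 3 lower (5 and 4), with Stfa3 and Krt6a highest and Tgm1 and Lor, which encodes loricrin, lowest (0.165). Of 23 EMT transcription factors, 1 was higher, Ets1, and 2 lower (4 and 2), Snai1 and Nfatc1 (0.316). Of 32 TGF-beta response genes, 2 were higher and 4 lower (4 and 6), with Pmepa1 3.35-fold higher and Id2 2.08-fold lower (0.425), and of 53 cell cycle genes 1 was higher, Mki67, and 0 lower (0 and 0, adjusted p = 0.512). Of 29 inflammatory genes, 1 was higher, Ccl7, and 3 lower, Cxcl3, Cxcl5 and Csf1 (2 and 5), with a median of -0.11 and a mean of 0.06 (0.642). Of 24 YAP and TAZ targets, 3 were higher and 3 lower (6 and 7), with a median of -0.05 and a mean of 0.02 (0.773). Of 28 interferon response genes, 0 passed by limma (0 and 0), Psmb8 having the smallest p (adjusted p = 0.0719, and 0.724 for the list). Of 21 Wnt pathway targets, 1 was higher, Apcdd1 (171 ± 0 against 4.5 ± 0.7), and 3 lower (2 and 5), Lef1, Wnt10b and Wnt10a, with a median of -0.06 and a mean of 0.18 (0.995). Of the 5 fibroblast markers 0 passed (0 and 0), with camera direction up and fry direction down (0.943), of 7 endothelial markers 1 was higher (1 and 0), Cdh5 (0.393), and of 5 melanocyte and nerve markers 1 was higher and 1 lower (1 and 1), Ncam1 and Mbp (0.724).

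For the cholesterol list the call was gained with TMM (adjusted p = 0.0361) and median-of-ratios scaling (0.039), and without library 2 of either knock-down. The heat shock list passed without Ntn1 knock-down library 1 or Unc5b knock-down library 1, and the unfolded protein list without Ntn1 knock-down library 2. The cell cycle list passed without Unc5b knock-down library 1 and the keratinocyte list without Unc5b knock-down library 2. All of these tests used the preset correlation of 0.01, against an estimated 0.591 for the cholesterol and 0.532 for the cell cycle list. Leaving out a library left 1 in its group. In all, limma called 1088 of 15330 genes different between the knock-downs, 636 higher and 452 lower in the Ntn1 knock-down, and 493 of them differed at least 2-fold. The count was 33 and 52 without Ntn1 knock-down library 1 and 2, 322 and 337 without Unc5b knock-down library 1 and 2, and 1837 and 1884 without empty vector library 1 and 2. It was 302 with no filter, 454 without the variance trend and 1856 with only the 4 libraries compared. Of 62 calls of named genes, 51 and 48 were lost without Ntn1 knock-down library 1 and 2, 32 and 20 without Unc5b knock-down library 1 and 2, 32 with no filter and 29 without the variance trend, and 0 changed direction.

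Many genes changed the same way in both knock-downs. The naming rule takes only genes with a mean of at least 100 in each comparison and no overlap between the groups. Under it the 5 highest on average were Tmem47, Adamts14, Mmp9, Serpinb2 and Zfp334. They rose 23.9-fold, 30.8-fold, 12.3-fold, 27.4-fold and 18.4-fold, in that order, in the Ntn1 knock-down. Among the lowest were Fras1, Cxcl12, Apob and Rspo3. Of the genes called in each comparison, 550 were higher in both knock-downs, 436 were lower in both and 20 were called in opposite directions. Independent lists of these sizes would share 72.7, 65.7 and 139 genes, and 100 simulated draws of unchanged groups with the same controls shared at most 1 in either direction. In such draws almost no gene is called, so their counts are no null for lists of this size. The log2 fold changes of the 2 comparisons correlated at r = 0.678 across genes, against 0.501 on average in the simulation. Their covariance was 0.336 against 0.0349, a difference of 0.301. The draws held only the spread between libraries of a group. An offset of the empty vector libraries from both knock-downs would also raise these values. The difference of 0.301 therefore does not measure an effect shared by the knock-downs. Genes are not independent replicates, and part of the excess over independent lists may come from the shared controls, which could not be split. Of the 436 genes lower in both, 323 (74.1%) were higher in empty vector library 2 than in library 1, against 51.8% of all genes tested. The number changed the same way in both was 986, and it was 302 and 318 without Ntn1 knock-down library 1 and 2, 608 and 445 without Unc5b knock-down library 1 and 2, 410 with no filter and 592 without the variance trend.

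**Figure D4:**
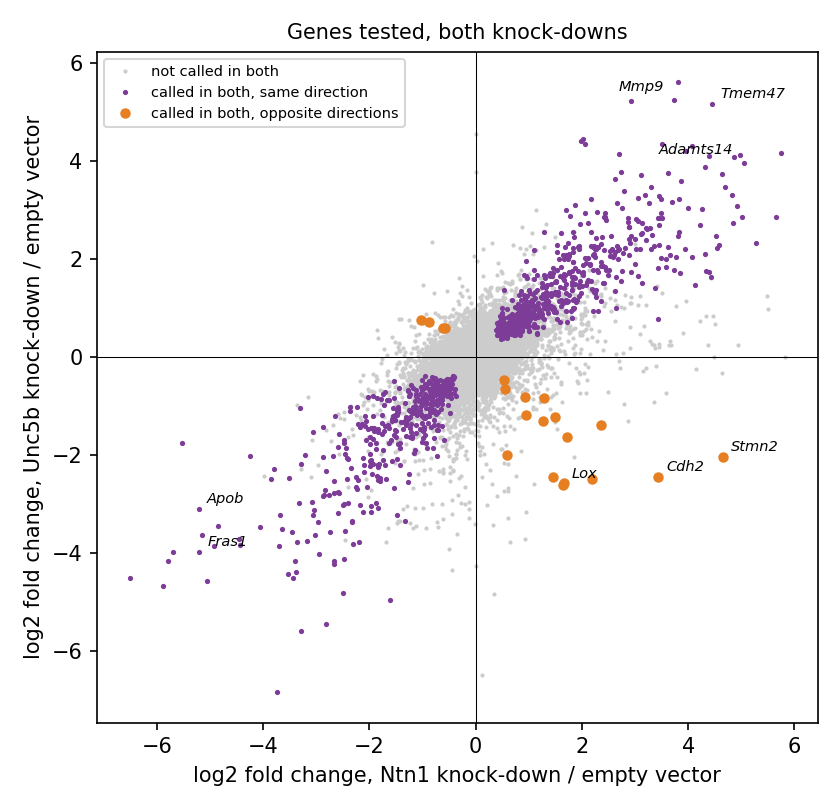
Log2 fold change of each of the 15330 genes tested in the Ntn1 knock-down (horizontal axis) and in the Unc5b knock-down (vertical axis), both against the empty vector. The 550 genes called higher in both and the 436 called lower in both are purple, the 20 genes called in opposite directions are orange, and the others are grey.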

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

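The tests for immune cells, for a stronger interferon response in the knock-downs and for fibroblasts were chosen only after the result was seen.

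Genes that differed between the knock-downs drew attention. Against the empty vector, Vim did not pass in the Ntn1 knock-down and Trp63 did not pass in the Unc5b knock-down. In the test of the difference between the knock-downs, Vim differed by 3.23, Cdh2 by 5.88 and Trp63 by -1.71 on the log2 scale, Ntn1 against Unc5b knock-down, and the mesenchymal and extracellular matrix list had adjusted p = 0.000129, but adjusted p = 0.567 with an estimated correlation and 0.126 with fry. There were 20 genes called in opposite directions against the empty vector, 16 of them higher and 4 lower in the Ntn1 knock-down. Unc5b, a targeted gene, is among the 16, beside Cdh2, Lox, Stmn2, Apcdd1, Gxylt2, Egln3, Flnc and Pmepa1, while Pom121, Pigm, Gpa33 and Mfsd1 are the 4. Apart from Unc5b, Cdh2, Lox, Stmn2, Apcdd1, Egln3 and Pmepa1, these genes were chosen after their values were seen.

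Of 43 mesenchymal and extracellular matrix genes, 10 were higher and 1 lower in the Ntn1 than in the Unc5b knock-down. Fibroblasts among the cells are argued against, since the median of Col1a1, Col1a2, Col3a1, Dcn and Lum in the Ntn1 knock-down was 14 per 20 M against 1055 for Vim, and the EPCAM and YFP sort would remove them. The lower depth of Ntn1 knock-down library 2 is argued against too, because without it Vim and Cdh2 kept adjusted p of at most 0.0439 and differences of 3.29 and 5.98. With TMM scaling the list had adjusted p = 0.00021 and 1.09 times its median, which speaks against scaling to the library total as the cause. As a hypothesis, the knock-downs may act differently on these genes, but each vector stands for 1 target, so a difference between vectors or cultures stays open and was not tested.

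Of 29 inflammatory genes, 16 were higher in each knock-down than in the empty vector. Immune cells are argued against, as the median of the 28 immune cell markers in the 4 knock-down libraries was 0 per 20 M and 3 of them reached a mean of 20. The median log2 fold change of the interferon list was -0.26 in the Ntn1 and -0.03 in the Unc5b knock-down. This argues against a stronger interferon response in the knock-downs than in the empty vector. A response to the vector that all groups share could not be tested, as the empty vector group carries a vector too. A single unusual empty vector library is argued against, as the inflammatory list kept adjusted p of at most 7.58e-07 and a median of at least 0.54 without either of them. What stays open is an effect of the knock-downs, as a hypothesis that was not tested, or of any hairpin against a vector without one, and the calls are lost with an estimated correlation (adjusted p = 0.354 and 0.359). With fry the calls were kept (adjusted p = 0.0148 and 0.00958).

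Genes lower in both knock-downs were higher in empty vector library 2 than in library 1 for 323 of 436 genes, with a median shift of 0.22 on the log2 scale, against -0.05 for the 550 genes higher in both. Scaling to the library total is argued against, as the median shift of all tested genes was 0.08 of that of these genes. More nuclear RNA in library 2, which had 0.593% of its total in Malat1 against 0.293%, cannot be told apart from a difference between cultures. Along the Malat1 level these genes shifted by 0.83 of that amount between the Unc5b knock-down libraries but by 0.04 between the Ntn1 knock-down libraries. The knock-down group as the reason for the lower level of these genes stays open and was not tested.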

How the results depend on the processing

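Of the settings and tests here, voom weights on estimated reads, the rescaling without rRNA-annotated and mitochondrial genes, the Malat1 covariate and the lists without Ntn1 and Unc5b were chosen only after the data were seen. No called result reversed under any setting run. Of the named genes called in the fit as reported or under the setting tried, 0 changed direction. Named genes called in neither were not checked for direction. For 3 list results called by neither test, fry and camera gave opposite directions. The cause of the changes below was not tested, except where fewer libraries or a stricter threshold make it. Counts are given as Ntn1 knock-down, Unc5b knock-down, Ntn1 against Unc5b knock-down, and both the same way, with 2314, 1835, 1088 and 986 in the fit as reported. They were 1289, 791, 302 and 410 with no filter, 1462, 1115, 454 and 592 without the variance trend, 4315, 3724, 2902 and 2117 with the Malat1 covariate, and 1099, 939, 493 and 532 with a 2-fold threshold added. With only the 4 libraries compared, they were 950 for the Unc5b knock-down and 1856 between the knock-downs. With TMM they were 2274, 1797, 1039 and 986, and TMM, median-of-ratios, the minimum mean of 100, both other pseudocounts, the rescaling and voom moved no count by over 1.5 times, nor did the 2-fold ratio without a test for the 3 comparisons of groups, the only counts it was run for. Leaving out each library in turn gave 509 to 2819, 669 to 2437, 33 to 1884 and 302 to 1458, where the lone library is assumed to vary like the other groups. A count test on recovered reads was not run, because the step was only estimated and whole reads at higher values are uncertain. Depth puts a floor of 3 reads at 5.90 to 9.17 in the scaled unit. In the simulated Ntn1 comparison, with 2 libraries a group, 6% of genes changed 1.5-fold were called, and depth was not varied there.

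With a replicate block, using the replicate numbers, the counts were 1465, 1102, 459 and 598, Unc5b in the Ntn1 knock-down had 0.60 (adjusted p = 0.0552) and the cholesterol list between the knock-downs 0.0481. Taken by replicate number, the deviations from the group means correlated at 0.16, -0.45 and -0.169 for the 3 pairs of groups. The numbers therefore give no common pairing. The -0.45, between the empty vector and the Unc5b knock-down, leaves open a shared difference between libraries in another order. The block changed no other call of a targeted gene or list. With it 12 of 86 calls of named genes were lost in the Ntn1 knock-down, 14 of 78 in the Unc5b knock-down and 20 of 62 between them, and Cdh1 between the knock-downs lost its call (adjusted p = 0.0668).

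Ntn1 in the Unc5b knock-down was called with TMM and median-of-ratios scaling (both -1.03) and with the Malat1 covariate (-0.95), with -1.38 to -0.61 when each library was left out. Unc5b in the Ntn1 knock-down had 0.60 with no filter (adjusted p = 0.0516) and without the trend (0.0636), with 0.57 to 0.62 when each library was left out. Ntn1 in its own knock-down and Unc5b in its own kept their calls under every setting run.

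For the lists, values are adjusted p. The tests that left out a library used the preset correlation of 0.01. The estimated correlation was 0.532 for the cell cycle and 0.591 for the cholesterol list, and 0 of 63 list tests passed with estimated values. It was 0.012 for the keratinocyte and -0.046 for the p53 list, near or below the preset. Yet their unadjusted camera p in the Ntn1 knock-down rose from 0.000159 to 0.0337 and from 0.0547 to 0.128. Correlated members alone therefore do not account for the calls lost with estimated values. With an estimated correlation the calls lost were inflammatory (0.354) and keratinocyte (0.354), YAP and TAZ (0.73) and cholesterol (0.746) in the Ntn1 knock-down, inflammatory (0.359), keratinocyte (0.623), YAP and TAZ (0.761) and netrin (0.761) in the Unc5b knock-down, and mesenchymal, netrin, hypoxia and epithelial (0.567 each) between them. With fry the calls lost were YAP and TAZ (0.122) and cholesterol (0.355) in the Ntn1 knock-down, netrin (0.209) and YAP and TAZ (0.202) in the Unc5b knock-down, and netrin, epithelial and mesenchymal (0.126 each) and hypoxia (0.105) between them. Those gained were p53 (0.0184), endothelial (0.0414) and melanocyte and nerve (0.0184) in the Ntn1 knock-down and melanocyte and nerve (0.00958) in the Unc5b knock-down. Those kept with fry were inflammatory (0.0148) and keratinocyte (0.0184) in the Ntn1 knock-down and inflammatory (0.00958) and keratinocyte (0.0413) in the Unc5b knock-down. With the Malat1 covariate cell cycle (0.0159) was gained in the Ntn1 knock-down and cholesterol (0.0329) and heat shock (0.0364) between the knock-downs. Cholesterol between the knock-downs was also gained with TMM (0.0361) and median-of-ratios scaling (0.039), and netrin in the Unc5b knock-down was lost without Ntn1 and Unc5b (0.111).

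Leaving out each library in turn, the adjusted p in the Ntn1 knock-down ranged over 0.000324 to 0.0988 for cholesterol, 0.0356 to 0.512 for Wnt, 0.00784 to 0.502 for mesenchymal, 8.03e-05 to 0.955 for cell cycle and 0.0154 to 0.668 for heat shock. In the Unc5b knock-down it was 0.0246 to 0.535 for mesenchymal, 0.0392 to 0.688 for TGF-beta, 0.0207 to 0.666 for Wnt, 0.000441 to 0.176 for netrin, 0.000164 to 0.894 for cell cycle, 0.00592 to 0.683 for hypoxia and 0.000115 to 0.894 for cholesterol. Between the knock-downs it was 0.0194 to 0.278 for heat shock, 2.69e-07 to 0.967 for cholesterol, 0.0282 to 0.326 for unfolded protein, 0.000583 to 0.724 for cell cycle and 0.041 to 0.537 for keratinocyte.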

Other observations

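The genes in this part were chosen after their values were seen, and no list test was made of them. The neurofilament genes Nefl and Nefm were listed at 0 in both empty vector libraries and were at 133 and 86 and at 181 and 122 in the Ntn1 knock-down, with at most 2 in the Unc5b knock-down. Gfra2, a receptor for glial-derived growth factors, was at 2 and 9 in the empty vector and 252 and 232 in the Ntn1 knock-down (limma adjusted p = 0.000494), and Uchl1, a ubiquitin hydrolase, at 4 and 9 and at 107 and 131 (adjusted p = 0.00109). The kinesin gene Kif5c rose by 0.96 ± 0.20 on the log2 scale in the Ntn1 knock-down and fell by 1.17 in the Unc5b knock-down, with adjusted p = 0.0141 and 0.00734. The homeobox genes Hoxa9 and Hoxa10 were at most 2 in the empty vector and Unc5b knock-down libraries and at 45 and 73 and at 97 and 104 in the Ntn1 knock-down.

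These further genes, also picked after their values were seen, were called in the same direction in both knock-downs, and their sizes were not compared. The hedgehog receptor gene Ptch1 fell by 1.26 in the Ntn1 and by 0.79 in the Unc5b knock-down on the log2 scale, with adjusted p = 0.000727 and 0.00684. The growth factor receptor gene Fgfr1 changed by -1.87 and -1.75 (adjusted p = 0.00318 and 0.00522), and Bdnf by -2.33 and -3.33 (0.00159 and 0.000456). The Notch ligand gene Jag1 rose by 1.70 and 0.95 (adjusted p = 0.000879 and 0.0132), whereas Notch1 fell by 0.64 and by 0.81 (0.0372 and 0.0182). The guidance ligand gene Slit2 rose by 1.49 and 1.29 (0.00636 and 0.0141), and Bmp7 by 1.53 and 2.16 (0.0144 and 0.00419).

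A group of 11 predicted genes, chosen after their values were seen, took 0.028% and 0.056% of the total in the empty vector libraries, 0.001% in each Ntn1 knock-down library and 0.004% and 0.005% in the Unc5b knock-down libraries.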
